A study of Mus musculus with 9 samples.

How the data were processed

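Stranded RNA-seq libraries were made from total RNA of Hepa1-6 cells and sequenced as paired ends of 150 bases on an Illumina NovaSeq instrument, per the labels' protocols. The protocols name an mRNA library kit and also a kit for ribosomal RNA depletion, and do not say which libraries were made with which. Reads were processed with fastp 0.23.4, featureCounts of Subread 1.5.1 and edgeR 3.12.1 on the GRCm38 build, per the submitters' processing notes. The aligner, the annotation and the strand setting of the counting are not given in the sources used here.

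One table per comparison was used, with values for its 6 libraries. The authors deposited RPKM values per library, and reads per kilobase cannot be told from fragments per kilobase here. As a check of the unit, 2 to the power of the deposited log2 CPM, divided by RPKM times exonic length in kb, had a median of 1.008, which does not show whether a normalization factor is included. The median offsets of the authors' log2 folds from the ratios of mean RPKM were -0.06, -0.12 and 0.07 in the order of the comparisons below, and their cause was not tested. The log2 fold changes, the F score of each gene and the p-values with adjusted values are those of the authors, per the file headers. All log2 folds were at least 1 and all p-values under 0.05, so each table holds genes selected for being higher. The ratio of p to adjusted p gave the rank of each gene and the number tested, as the number that gave the largest share of whole ranks: 15142 for P-Por-Os+US against control, 15270 for P-Por-Os against control and 15074 for P-Por-Os+US against P-Por-Os. The shares of whole ranks were 78.7, 72.5 and 66.7 percent of the rows of these tables, since adjusted values that tie do not give ranks.

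Depth was read from the RPKM values. RPKM times exonic length is a whole number of reads at the right depth, and between 84.7 and 90.1 percent of values under 400 reads were whole within 0.05 at the depth found, against 11.7 to 16.6 percent at other depths. The exonic lengths came from GENCODE M21, on the same build, where 208 of the 217 symbols occurred once and 9 did not. Such reads were used to state depth, not for a count test. Depth sets precision: the control mean of Krt16, 0.0583 RPKM, rests on 2 to 4 reads per library.

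Groups were taken from the labels. The design fixed before the data were examined asked for a count test or, for normalized values, limma on log2(value + 1) over all 9 libraries or over the 6 of a table, and for counting the rows of a table of selected genes. Both of the latter apply here: the main value of each comparison is the number of listed genes, and limma 3.58.1 in R 4.3.3 was run on the 6 libraries of each table with a trend of variance on mean, a pseudocount of 1, a minimum mean of 1 RPKM and Benjamini-Hochberg adjustment over the genes of the table. A log2 fold of at least 1 with an adjusted p under 0.05 counted as passing. Because the genes were selected on the same libraries, the adjusted p-values are too small. They also depend on the filter for P-Por-Os against control, where the prior degrees of freedom were 41.1 with the filter and 7.2 without it. A fit of all 9 libraries used the 28 genes with values in each of them, without the filter. Where a library was left out or a block was added, the listing criterion was evaluated again as an unadjusted limma p under 0.05 on log2(RPKM) and a ratio of means of at least 2 after the median offset to the authors' folds, in place of the authors' test. No count test was run, as RPKM values are not counts. No enrichment test was run on the 24 gene lists fixed beforehand, as values were given for selected genes only.

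The limma script was tested on simulated data, with 1000 genes drawn as negative binomial counts at the levels, spreads and depths of the listed genes and 200 of them changed, 100 by each fold. For P-Por-Os+US against control it ran on 513 genes and recovered 94.5 percent of 4-fold changes (69 of 73 run) and 20.7 percent of 2-fold changes (12 of 58 run). In each comparison the shares leave out changed genes that fell below the filter. For P-Por-Os against control it ran on 536 genes and recovered 94.4 and 22.4 percent, and for P-Por-Os+US against P-Por-Os on 507 genes with 92.9 and 22.2 percent. It called 0 unchanged genes in each. With a pseudocount of 0.1 and no filter it called 1, for P-Por-Os+US against control. The spreads came from selected genes and most simulated genes were unchanged, unlike in the tables, so these results may not carry over to them. A true 2-fold change lies at the fold minimum, which the pseudocount lowers further. With 3 libraries against 3, an exact permutation test cannot give a two-sided p under 0.1, so none was used for single genes.

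Overlap of the lists was set beside the number expected of independent lists and beside 100 simulated sets of unchanged groups that share 3 controls, at the levels and spreads of the listed genes, not at those of all genes tested. Shared reads were assessed by exonic overlap on either strand and by shared 31-base words of transcripts. A word and its reverse complement counted as the same, so shared words do not depend on strand. Overlap on the opposite strand was added after the first result was seen. Genes were named by a rule fixed beforehand: the 10 highest and 10 lowest folds among changed genes of each comparison (no lower gene was listed), up to 4 listed members of each gene list by fold, and genes listed in all 3 comparisons. Hist1h1b, Hist2h2bb, Clca3a1, Clca3b, Heatr1, Hmgn2, S100a14, Sprr1b, Sprr2e, the genes that passed limma between the treated groups and the exceptions to non-overlap were named after their values were seen. Alternatives covered the pseudocount, the filter, a replicate block, each library left out, stricter thresholds, gene type, read sharing and the authors' scaling. Figures were drawn with matplotlib 3.10.9.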

Results

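RNA was sequenced from Hepa1-6 cells, a mouse hepatocarcinoma line, in 9 libraries that fall into 3 groups of 3. The control group received no treatment per the labels and PBS per the series description. A second group received the material named P-Por-Os at 25.57 µg/mL, and the last received P-Por-Os at 25.57 µg/mL together with ultrasound (P-Por-Os+US). The design asks how the mRNA of these cells differs after P-Por-Os alone and after P-Por-Os with ultrasound. The deposited tables give RPKM, reads scaled to gene length and library total, per library for selected genes only, 217 distinct genes over 3 comparisons. Every row is a gene that was higher in the first group of its comparison, with a log2 fold of at least 1 and an unadjusted p under 0.05 in the authors' deposited table. Genes that fell, or rose by less, are not described here, and nothing below says that they did not change. The whole-read steps in low RPKM values placed the library totals behind the RPKM values between 34738000 and 37667000 reads. The labels do not say whether the libraries of a group came from separate cultures, so the tests measure the spread between these libraries, which may be technical.

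P-Por-Os without ultrasound was compared with control to ask what the material changed by itself, and 160 genes were listed as higher, with 0 listed as lower. The largest named group was the replication-dependent histones, which package newly made DNA: 18 of 60 members of that list were listed. Hist1h1b, a linker histone, was at 237 ± 6.78 RPKM after P-Por-Os against 91.5 ± 11.2 in control (SD, n = 3 each). Hist1h2ah was at 1.21e+03 ± 30.7 RPKM against 388 ± 133, Hist2h2ac at 961 ± 42.6 against 344 ± 67.2, Hist1h2ae at 189 ± 13.8 against 58.3 ± 16.3, and Hist1h1a at 13.7 ± 0.502 against 4.82 ± 0.669 (SD, n = 3 each). In the authors' deposited table the log2 folds of the 18 genes ran from 1.02 to 1.59, with a median of 1.26, and Hist1h1b had the smallest p of all 15270 genes tested. Other members had larger p-values in the authors' deposited table, such as 1.8e-09 for Hist1h1a, 5.9e-06 for Hist2h2ac, 0.0028 for Hist1h2ah and 0.0055 for Hist1h4b. Control replicate 1 lay lowest of the control libraries for these genes, with a median deviation of -0.35 from the control mean on the log2 scale, against -0.18 for 115 listed genes left after histone-named genes, models that overlap or share words with them, and satellite-like models were set aside. Without that library, the log2 ratios of mean RPKM of the 18 genes ran from 1.04 to 1.49, with a median of 1.16 against 1.38 with all libraries. The listing criterion, evaluated again with limma, was then met by 13 of the 18, and the other 5 fell to between 0.92 and 0.97 on the authors' scale, below the minimum of 1. Of the 18 genes, 12 share at least 50 percent of their 31-base words with other listed genes, so the split of reads among histone copies is uncertain.

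**Figure D1:**
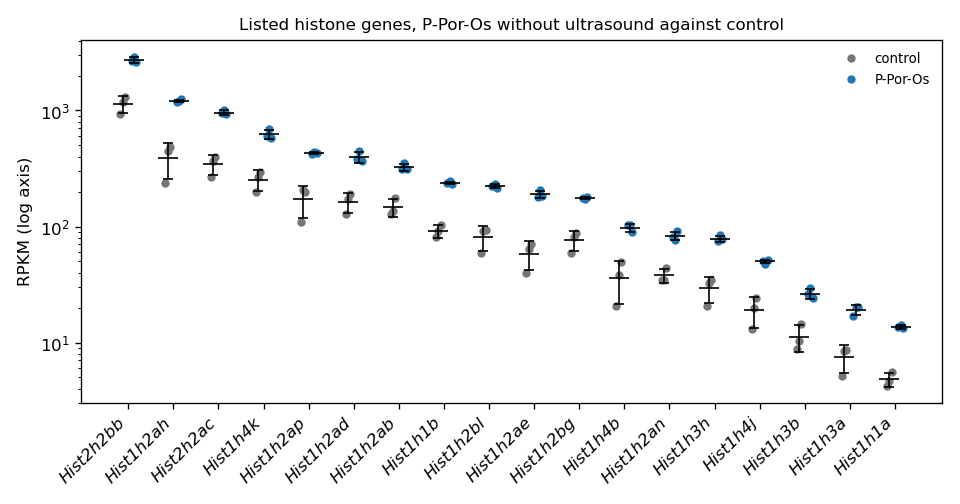
RPKM on a log axis of the 18 listed replication-dependent histone genes in the 3 control libraries (grey) and the 3 P-Por-Os libraries (blue). Points are libraries, and black marks are group means with SD. Every P-Por-Os point lies above every control point of the same gene, from Hist2h2bb at the top to Hist1h1a, whose means were 13.7 and 4.82 RPKM.

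Krt16, Krt76 and Lce1h had the 3 highest folds of the table after P-Por-Os alone, from control levels below 1 RPKM. Krt16, a keratin of stressed epidermis, was at 0.695 ± 0.0188 RPKM against 0.0583 ± 0.019 in control (SD, n = 3 each), which corresponds to 38 to 40 reads per library against 2 to 4. Krt76, another keratin, was at 0.526 ± 0.0902 RPKM against 0.0834 ± 0.0207, and Lce1h, a cornified envelope gene, at 1.89 ± 0.22 against 0.309 ± 0.123 (SD, n = 3 each). Ivl, which encodes the envelope protein involucrin, stood at 14.0 ± 0.927 RPKM against 2.88 ± 0.172, and Edn1, which encodes the vasoconstrictor endothelin, at 0.669 ± 0.142 against 0.142 ± 0.0545 (SD, n = 3 each). The authors' deposited table gives log2 folds of 3.39 for Krt16, 2.51 for Krt76, 2.45 for Lce1h, 2.15 for Ivl and 2.12 for Edn1. The other genes among the 10 with the highest folds were Gm10717, Gm10718, Gm10801, Gm10800 and Gm26870, gene models on chromosomes 2 and 9 whose words recur in one another. Gm10800, on chromosome 2 from 98666547 to 98667301, was at 187 ± 2.80 RPKM against 36.7 ± 5.55 (SD, n = 3 each).

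Metal-responsive genes were also higher after P-Por-Os alone. Of the 8 members of the metallothionein and metal response list, 3 were in the table: Mt1 and Mt2, small proteins that bind zinc and copper, and Slc30a1, which exports zinc from the cell. Mt2 was at 29.7 ± 2.15 RPKM against 8.41 ± 2.10 in control, Mt1 at 9.69 ± 0.792 against 4.32 ± 0.852, and Slc30a1 at 1.17 ± 0.0758 against 0.386 ± 0.0324 (SD, n = 3 each). The authors' deposited table gives log2 folds of 1.71, 1.05 and 1.46 for Mt2, Mt1 and Slc30a1. Single members of 5 other lists were higher. Fosb, an immediate early transcription factor, was at 6.24 ± 1.13 RPKM against 2.42 ± 0.125, and Csf2, which encodes the cytokine GM-CSF, at 19.6 ± 1.32 against 7.16 ± 1.30 (SD, n = 3 each). Rrm2, a subunit of ribonucleotide reductase, was at 16.9 ± 0.574 RPKM against 7.58 ± 1.02, Angptl4, a PPAR target, at 2.45 ± 0.0929 against 1.03 ± 0.135, and Cd14, an endotoxin co-receptor known as a myeloid marker, at 4.03 ± 0.246 against 1.40 ± 0.105 (SD, n = 3 each). None of the 17 other lists, which include antioxidant defence, ferroptosis, heat shock, unfolded protein response, p53 targets and apoptosis, had a member in this table.

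Of the 160 genes, 101 had a mean of at least 1 RPKM, and all 101 differed from control in limma, with an adjusted p of at most 2.9e-06 when genes below that mean were left out of the fit and at most 0.0017 when they were kept in. Of these, 70 also kept a log2 fold of at least 1 on the log2(RPKM + 1) scale, which understates folds of low genes. Every P-Por-Os library lay above every control library for 159 of the 160 genes, the exception being Lipt2. Chance gives 5 percent for unselected genes, but these had been chosen on the same libraries, so neither count is independent evidence. Only 120 of the 160 remained when gene models that overlap or share words were counted once, and 59 had a mean below 1 RPKM.

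P-Por-Os with ultrasound was compared with control to ask what the combination changed, and 61 genes were listed as higher, with 0 listed as lower. The metallothioneins stood out. Mt2, on chromosome 8 from 94172664 to 94173568 (GRCm38), was at 141 ± 5.78 RPKM against 8.41 ± 2.10 in control, and Mt1, from 94179082 to 94180327 on the same chromosome, at 20.2 ± 1.68 against 4.32 ± 0.852 (SD, n = 3 each). Slc30a1 was at 1.43 ± 0.0631 RPKM against 0.386 ± 0.0324 (SD, n = 3 each). The authors' deposited table gives log2 folds of 4.02 for Mt2, 2.17 for Mt1 and 1.82 for Slc30a1, and a fold of 16.2 for Mt2 on the linear scale. RP23-98C9.5, a clone-named gene model, was listed beside Mt2 at 31.1 ± 1.25 RPKM against 1.87 ± 0.451 (SD, n = 3 each). Its ratio to Mt2 was 0.221 in the mean of 9 libraries with a coefficient of variation of 0.90 percent (SD over mean). It is included in all counts of genes given here.

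Other groups were represented by 1 or 2 genes each. Hmgcs1, an enzyme of cholesterol synthesis, was at 28.6 ± 2.78 RPKM after P-Por-Os+US against 13.5 ± 1.54, and Insig1, which restrains that pathway, at 1.71 ± 0.293 against 0.750 ± 0.111 (SD, n = 3 each). They were 2 of 33 members of the cholesterol and fatty acid synthesis list. Rsad2, an interferon-induced antiviral gene, was at 0.919 ± 0.127 RPKM against 0.280 ± 0.0892, and Cxcl5, a neutrophil chemokine, at 8.39 ± 0.455 against 3.74 ± 0.536 (SD, n = 3 each). Fosb was at 8.33 ± 1.33 RPKM against 2.42 ± 0.125 and Cd14 at 3.44 ± 0.156 against 1.40 ± 0.105 (SD, n = 3 each). Nipal1, at 0.412 ± 0.144 RPKM against 0.082 ± 0.0255, and Gbe1, the glycogen branching enzyme, at 0.318 ± 0.0544 against 0.0907 ± 0.0616, had large folds at low levels (SD, n = 3 each). The authors' deposited table gives log2 folds of 2.26 for Nipal1, 1.73 for Gbe1, 1.72 for Fosb, 1.67 for Rsad2, 1.13 for Insig1 and 1.02 for Hmgcs1. Gm38217, a model of undetermined type, and 1700034H15Rik, an antisense model, were also among the 10 highest folds with RP23-98C9.5. The exons of 1700034H15Rik overlap Slc30a1 on the opposite strand over 7.7 percent of their length, and only reads in that part depend on strand. None of the 18 other lists had a member in this table.

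Of the 61 genes, 41 had a mean of at least 1 RPKM, and all 41 differed in limma with an adjusted p of at most 0.009. With a log2 fold of at least 1 on the log2(RPKM + 1) scale, 18 remained. With a pseudocount of 0.1, that count was 40. The groups did not overlap for 59 of the 61 genes, the exceptions being 9330151L19Rik and Kif5a. Chance gives 5 percent in this direction for unselected genes, but these were selected on the same libraries for being higher, so neither this count nor the adjusted p is independent evidence. Protein-coding genes made up 32 of the 61.

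The addition of ultrasound to P-Por-Os was examined by comparing P-Por-Os+US with P-Por-Os, and 27 genes were listed as higher with ultrasound. Mt2 rose from 29.7 ± 2.15 to 141 ± 5.78 RPKM and Mt1 from 9.69 ± 0.792 to 20.2 ± 1.68 (SD, n = 3 each). Rsad2 was at 0.919 ± 0.127 RPKM with ultrasound against 0.285 ± 0.00432 without, and Insig1 at 1.71 ± 0.293 against 0.828 ± 0.112 (SD, n = 3 each). Epcam, an adhesion protein of hepatic progenitors, was at 5.25 ± 0.468 RPKM against 2.68 ± 0.184, and Nrep at 0.454 ± 0.0138 against 0.176 ± 0.0754 (SD, n = 3 each). Nipal1 was at 0.412 ± 0.144 RPKM against 0.174 ± 0.0326 (SD, n = 3 each). The authors' deposited table gives log2 folds of 2.33 for Mt2, 1.76 for Rsad2, 1.43 for Nrep, 1.30 for Nipal1, 1.13 for Mt1, 1.11 for Insig1 and 1.05 for Epcam. Gm10371, Gm11915, Gm34176, Gm43912, Rpl9-ps6 and RP23-98C9.5 were the other models among the 10 highest folds, and 20 of 24 lists had no member in this table.

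All 20 genes with a mean of at least 1 RPKM differed between these groups in limma, with an adjusted p of at most 0.011, and the groups did not overlap for any of the 27. Chance gives 5 percent for unselected genes, but these were selected on the same 6 libraries, so neither value is independent evidence. Only Mt2, RP23-98C9.5, Gm11915 and Gm34176 kept a log2 fold of at least 1 on the log2(RPKM + 1) scale. That count was 7 without P-Por-Os+US replicate 3 and 9 with a pseudocount of 0.1. Protein-coding genes made up 12 of the 27.

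Both lists against control shared 21 genes, where lists of 61 and 160 drawn independently from 15142 genes would share 0.64. Unchanged groups simulated against common controls shared 8.91 genes on average over 100 draws and 15 at most, but their lists held 39.7 genes on average, fewer than 61 and 160, so the simulated and observed overlaps are not like for like. Among the 21 were Mt1, Mt2, Slc30a1, Fosb, Cd14, Clca3b and Clca3a1, which encode chloride channel accessory proteins, Heatr1, a ribosome biogenesis factor, and Hmgn2, a nucleosome-binding protein. Without control replicate 1, 12 genes met the criterion, evaluated again with limma, in both comparisons. The same 3 control libraries entered both comparisons and are too few to be split, so part of the excess over 0.64 may come from them, and no shared effect is inferred.

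Among those 21 genes, 8 had an adjusted p under 0.05, with no fold minimum, between P-Por-Os+US and P-Por-Os. The limma fit used all 9 libraries on log2(RPKM + 1). Its adjustment ran over 28 genes, of which 10 had been listed as higher in this same contrast, so the adjusted p-values are too small. Of the 8, Mt2, RP23-98C9.5, Mt1, Gm38217, Fosb and Slc30a1 were higher with ultrasound, and Clca3a1 and Clca3b were lower. Clca3a1 was at 2.31 ± 0.0981 RPKM with ultrasound against 3.30 ± 0.238 without (SD, n = 3 each), and its difference of -0.38 ± 0.09 (SE) on the log2(RPKM + 1) scale had a limma adjusted p of 0.0022. Clca3b was at 29.6 ± 3.64 RPKM against 39.5 ± 1.05 (SD, n = 3 each), with a difference of -0.41 ± 0.16 (SE) and a limma adjusted p of 0.035, which became 0.052 with a pseudocount of 0.1. Slc30a1 differed by 0.17 ± 0.07 (SE) with a limma adjusted p of 0.049, which became 0.13 with a pseudocount of 0.1. With that pseudocount and the authors' scaling, the limma adjusted p was 0.11 for Clca3b and 0.058 for Slc30a1. Cd14, Heatr1 and Hmgn2 did not reach an adjusted p under 0.05, at differences of -0.18, -0.19 and -0.19. Without P-Por-Os replicate 2, 5 of the 21 genes reached it.

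**Figure D2:**
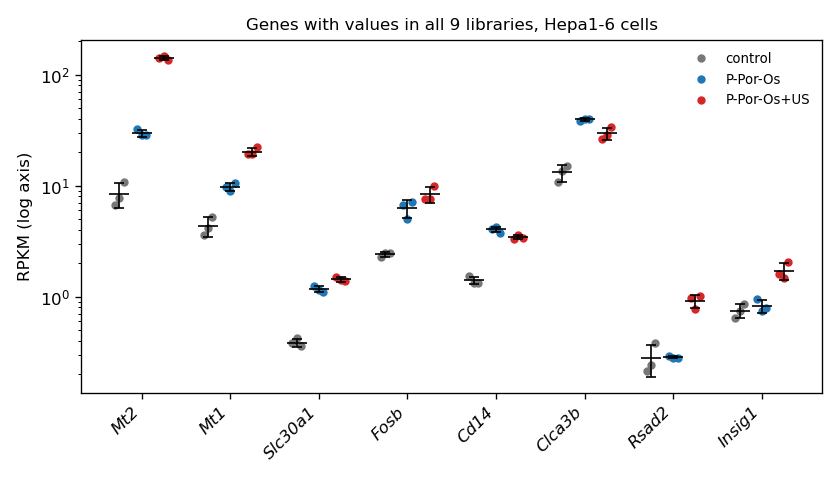
RPKM on a log axis of 8 genes in the control (grey), P-Por-Os (blue) and P-Por-Os+US (red) libraries. Points are the 3 libraries of a group, and black marks are means with SD. Mt2 climbs from 8.41 to 29.7 and 141 RPKM across the groups, while Rsad2 and Insig1 are near control without ultrasound, at 0.285 and 0.828 RPKM.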

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

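The settings added after the data were seen were the adjusted p under 0.05, Bonferroni over all genes tested, one model per read-sharing group, limma in place of the authors' test, the joint change of pseudocount and filter, no fold minimum, the authors' scaling, and leaving out controls for the overlap. Of 122 alternative counts, 92 lay within 1.5 times the main count. In the order P-Por-Os+US against control, P-Por-Os against control and P-Por-Os+US against P-Por-Os, the listed counts of 61, 160 and 27 became 4, 11 and 3 with an absolute log2 fold of at least 2, and 21, 73 and 10 with Bonferroni over the genes tested. Protein-coding genes were 32 of 61 and 12 of 27, and 101 of 160 had a mean of at least 1 RPKM. Leaving out each library gave 42 to 59, 120 to 157 and 22 to 24 genes, the 42 and the 120 both without control replicate 1.

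Genes passing limma numbered 18, 70 and 4. They became 51, 135 and 12 with a pseudocount of 0.1 and no filter, 40 and 9 in the first and last comparison with a pseudocount of 0.1 alone, 41 and 20 there with no fold minimum, 3, 3 and 2 with a log2 fold of at least 2, and 8, 45 and 1 for protein-coding genes. Leaving out each library gave 13 to 24, 65 to 74 and 3 to 7, the 7 without P-Por-Os+US replicate 3. The pseudocount lowers the folds of low genes, which raises the counts at 0.1 by construction, and the cause of the other shifts was not tested.

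The overlap of 21 genes became 13 for protein-coding genes, 0 with a log2 fold of at least 2 in both, and 12 to 20 without a control library, the 12 without control replicate 1. Members of the gene lists, 9, 26 and 5, became 2, 0 and 1 with a log2 fold of at least 2. The 8 genes that differed with ultrasound became 5 to 8 without a library. Labels give the groups the same replicate numbers, but same-numbered libraries did not deviate together (r from -0.17 to 0.16) and 2 of 9 correlated best with their own number. With a replicate block the listing criterion, evaluated with limma, held for 60, 158 and 26 genes, limma passed 18, 70 and 4, and 8 genes differed with ultrasound. The named genes were selected on the same libraries for being higher, so their direction and adjusted p could hardly change. The following agreement is therefore no independent evidence. Over 50 named gene and comparison pairs, 400 of 400 alternative values kept their direction and an adjusted p on the same side of 0.05. The log2 fold crossed 1 in 37 of them, 24 upward, such as Krt16 after P-Por-Os (0.68 to 2.34 with a pseudocount of 0.1), and 13 downward, such as Mt1 after P-Por-Os (1.02 to 0.91 without control replicate 1). Count tests by edgeR or DESeq2, their normalizations and count filter, matching by identifier, and camera or fry were not run, since the tables hold RPKM and symbols of selected genes.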

Other observations

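The tests of the control deviations, the histone folds with a library left out, the metallothionein library dependence, the clone-named model, the chromosome 3 cluster and the splits of the 9-library fit were chosen after the results were seen. Beyond the comparisons, the ranks in the authors' deposited table place at least 5479 and at most 6091 of 15142 genes under an adjusted p of 0.05 for P-Por-Os+US against control. By the same reading, between 5548 and 7270 of 15270 genes did so for P-Por-Os against control in the authors' deposited table, and between 2483 and 5856 of 15074 for P-Por-Os+US against P-Por-Os. The listed genes are thus 0.4, 1.05 and 0.18 percent of those tested, and 3 genes with a smaller p than Mt1, the best listed gene against control with ultrasound, are absent from that table.

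For the histone rise after P-Por-Os alone, leaving out any of the 6 libraries left the log2 ratios of the 18 genes at 1.04 or more. The lowest was reached without control replicate 1, where the largest limma SE was 0.16. In these libraries the rise thus did not rest on control replicate 1 alone. The genes were selected on the same libraries for their fold, which favoured this outcome, so it is no independent evidence. Without control replicate 1, the 13 of 18 genes that met the criterion lay between the bounds set beforehand. Whether that library decides the listing therefore cannot be told. The other 5 lay close to the fold minimum. Shared reads may account for part of the number of histone and miRNA models listed. The measure was a same-strand exon overlap, or at least 50 percent of words shared on either strand, with 1 other listed gene. It was met by 76.7 percent of the listed histone genes and predicted miRNA models, and by 66.7 percent of the histone genes alone. Of 12 miRNA models, 10 lie opposite listed histone exons. These 10 share reads with those exons only if the counting ignored strand, and its strand setting is not given. Hist1h1a and Hist1h1b share 0.3 percent of their words with other listed genes, yet had log2 ratios of 1.51 and 1.38. Whether sharing changed the folds of the other histone genes was not tested. A varying amount of RNA without a poly(A) tail cannot be told apart, as the control deviations of histone and satellite-like models differed by up to 0.18 on the log2 scale, between the bounds, which were set after the control values were seen. A higher share of dividing cells was not tested.

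Of the satellite-like gene models on chromosomes 2, 9 and 14, chosen after their values were seen, 5 of 10 (50 percent, exactly the bound set) share at least 50 percent of their words with 1 other listed gene, and 6 of 10 with all other listed genes pooled. Some may thus be counted from the same reads, though each is included in the 160 listed genes. The 10 models had folds of 3.27 to 4.89 in the authors' deposited table.

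For the rise of metallothioneins with ultrasound, leaving out any of the 6 libraries left the log2 ratio of Mt1 or Mt2 at 0.99 or more, and the median log2 ratio of the 26 other genes with 9 values was 0.16, with a median absolute deviation of 0.56, against 1.06 for Mt1 and 2.25 for Mt2. Those 26 include RP23-98C9.5, and without it the median was 0.12 and the deviation 0.49. All 26 were selected for being higher in a comparison, some of them with ultrasound, so they give no neutral baseline for scaling. Mt1 and Mt2 were selected on the same libraries. In these libraries the rise did not rest on a single library, but this is no independent evidence. The values argue against a scaling factor shared by these 26 genes as the whole cause. The constant ratio of RP23-98C9.5 to Mt2 (coefficient of variation 0.90 percent) is consistent with the same reads being counted in both. A response to ultrasound with P-Por-Os remains a hypothesis, and none of the 9 libraries had ultrasound without P-Por-Os.

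Of 75 protein-coding genes in the epidermal cluster on chromosome 3, from 90511034 to 93564643 (GRCm38), 5 were listed after P-Por-Os alone (Ivl, Lce1h, S100a14, Sprr1b and Sprr2e) where 0.79 would be by chance, with a hypergeometric p of 0.0011, counting all 75 as tested. The cluster was chosen because its genes were seen in the list, so the p is too small.

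The 10 splits of the 6 libraries are too few for a share under 0.05. The real groups gave 18, 70 and 4 genes passing limma in the 3 comparisons. In the 9-library fit they gave 8 with an adjusted p under 0.05, without a fold minimum. The highest of the other splits was 0 in each, and 1 split, the real one, gave as many. The genes of each table were selected on the real groups, so low counts in the other splits of the 3 comparisons were set by that selection and are no evidence. The 21 genes counted in the 9-library fit were selected against control, and 3 of them, Mt1, Mt2 and RP23-98C9.5, also between the treated groups. Of the 28 genes in its adjustment, 10 were listed between the treated groups.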
